A study of Mus musculus with 28 samples.

How the data were processed

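RNA was extracted with Trizol and checked on a Bioanalyzer, and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The series holds 28 samples, 12 livers and 12 muscles at 40 d and 2 of each tissue at 24 h. The authors deposited 3 tables of FPKM values (fragments scaled to gene length and library size), per the file headers, one for each tissue at 40 d and one for 24 h. The builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counter and the use of strand in counting are not given in the sources used here. The tables list 54163 genes for liver, 54189 for muscle and 54501 for 24 h, of which 53801 carry Ensembl identifiers and the rest, 362, 388 and 700, are gene models that took at most 0.22% of the reads. All 28 columns of sample values were used.

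The deposited FPKM values were whole multiples of 1 read for 100% of values, within a tolerance of 0.01, so the number of reads per gene was recovered with each gene's exonic length from the tables. The denominators at 40 d matched the total scaled by median-of-ratios size factors (0.0% off), so the libraries of a tissue were already scaled to each other by the authors' values. At 24 h the denominators were off such factors by −10.271% to −10.839%. This offset was nearly the same in all 4 libraries, so it largely cancels in ratios between them. The 3 tables were normalized separately. Tests were therefore made only within a table, and the difference between tissues is a difference of effects that were each taken within a table. Libraries held 16.8 to 18.9 M reads on genes in liver and 16.1 to 19.9 M in muscle at 40 d. Mitochondrial genes took 3.73% to 6.54% of reads in liver and 5.1% to 10.53% in muscle at 40 d, and the 10 most abundant genes 15.9% to 19.9% and 17.4% to 22.5%. At this depth a short gene at 1 FPKM has few reads, and its value is limited by counting error. No libraries of a group were duplicates: chi-square per degree of freedom between libraries of a group was 12.38 to 185.59. The labels number the mice, and the libraries of a group are taken as separate mice as far as the labels say.

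Groups were taken from the labels. Samples from either drug alone were not analysed here. Each gene was tested on log2(FPKM + 1) with limma's moderated test with a trend (R 4.3.3, limma 3.58.1), two-sided, 6 against 6, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with at least 1 FPKM in at least 6 of the 12 libraries of a tissue were tested. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, which asks whether the genes of a list move on balance in one direction, and with an exact permutation of list means over all 924 relabellings. The difference between tissues was a contrast in a limma fit of the 24 libraries at 40 d. At 24 h no test was made. The log2 ratio was computed with the same pseudocount, and the median of each list was placed among 10000 random lists of the same size and like mean expression. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

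The gene lists, the tests, the alternatives set in advance and the rule for naming genes were fixed before the data were examined. The tables turned out to hold FPKM, so the tests were made on the log scale. The plan also allowed count tests as an alternative if reads could be recovered. They could be, but the planned count tests were not run, and limma voom on the recovered reads took their place. For each tissue at 40 d, the rule names the 8 genes with the largest positive and the 8 with the largest negative fold change past the threshold, leaving out predicted-gene symbols, the 3 members with the smallest p in each list that passed, the 8 genes with the smallest p where fewer than 10 pass, and a fixed set of drug targets and metabolic genes. At 24 h it names the 6 largest and the 6 smallest log2 ratios among genes with a mean of at least 5 FPKM, and the fixed set. For the difference between tissues it names the 6 genes with the smallest adjusted p. Genes named for other reasons are said to be so where they appear, and the values at 24 h of genes named at 40 d are given for comparison. Not every gene that the rule allows is named.

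The tests were checked on simulated reads with the gene means, spread within groups, gene lengths and depths of the real libraries. The scripts run this check ahead of the tests, but it was first run after the first fits to the real values. For liver, with 11097 genes in the simulation, 34 of 66 genes changed 1.5-fold were called, 58 of 64 changed 2-fold and 65 of 65 changed 4-fold, with 11 false calls. For muscle, with 11727 genes, 37 of 65, 61 of 67 and 65 of 65 were called, with 4 false calls. For the difference between tissues, with 9482 genes, 34 of 67, 57 of 67 and 64 of 66 were called, with 7 false calls. With nothing changed, 0 genes were called in either tissue. All 4 lists changed 1.5-fold were called in each tissue with 0 false calls, and at 24 h all 4 were placed at the high end, with 2 further lists there in liver and 0 in muscle. The simulated genes varied independently of each other, whereas correlation within the real liver lists was estimated at up to 0.91. The false calls among lists therefore do not show how the list tests behave on correlated lists.

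Genomic positions are those of GRCm38. Of the 53801 Ensembl identifiers, 53620 were found in the annotation used here, 97.1% with the same coordinates and 96.5% with the same exonic length as in the tables. Genes that share 60% or more of their exons with others, and the neighbours Ang and Rnase4, are reported as uncertain where they appear. Smaller shares leave some uncertainty in other genes that the text names: on the same strand mt-Atp8 (21.1%), Coro1b (13.5%) and mt-Atp6 (6.5%), and on the other strand Ccnd1 (23.4%), Pklr (22%), Alox5ap (13.3%), Myh7 (13.3%), Mogat1 (12.8%), Icam1 (11.7%), Acsl1 (9.9%), Acss2 (9.1%), Slc37a1 (8.3%) and Ptgis (6.1%). Alternatives tried were another pseudocount (0.1), no filter and a stricter filter (mean of 5 FPKM), median-of-ratios and quantile scaling, array weights, the label numbers 2 and 5 alone, leaving out each mouse, a rank test, other list tests and the label number as a block.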

Results

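RNA was sequenced from liver and muscle of obese mice given a combination of aspirin and trimetazidine or the solvent alone. The animals were male C57BL/6J mice homozygous for the ob allele of Lep, which leaves them without functional leptin, so that they overeat and become obese. From 4 weeks of age, 30 mice ate the AMLN diet for 20 weeks, a food that takes 40% of its calories from fat and 20% from fructose, holds 2% cholesterol by weight, and is used to produce fatty, inflamed livers (nonalcoholic steatohepatitis). Aspirin (acetylsalicylate) acetylates the cyclooxygenases Ptgs1 and Ptgs2, and trimetazidine is an inhibitor of the mitochondrial thiolase step of fatty acid oxidation. The drugs were injected together into the abdomen every day, aspirin at 3.0 mg/kg and trimetazidine at 5.0 mg/kg. The series asked whether the combination improves metabolic disease, and its title describes the drugs as enhancers of exercise.

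At 40 d, each tissue had 6 libraries from treated and 6 from vehicle mice. At 24 h, each tissue had 1 library per group. The mice are named here by the numbers in their labels, 2_1, 2_3, 2_4, 2_5, 3_2 and 6_1 for vehicle and 4_5 and 5_1 to 5_5 for treated. No first digit occurs in both groups, so anything that goes with it cannot be separated from the treatment. The livers at 40 d held 18.22 ± 0.53 M reads on genes in the vehicle group and 17.95 ± 0.68 M in the treated group (SD, n = 6 each). The muscles at 40 d held 17.64 ± 1.29 M and 17.98 ± 1.31 M. The 4 libraries at 24 h held between 16.1 and 17.4 M. Values are FPKM, mean ± SD over 6 libraries unless stated otherwise, and log2 fold changes are treated over vehicle on the log2(FPKM + 1) scale, which understates the change of low genes.

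The first comparison asked what 40 d of the combination did to the liver. Transcripts of the acute phase proteins, which the liver secretes during inflammation, were higher in treated livers, with 18 of 19 members up and a median log2 fold change of 0.97. The list of neutrophil transcripts was higher by a median of 1.98 on the log2 scale over 5 measured members, and genes of fatty acid synthesis went the other way, all 21 of them lower with a median of −0.75. These 3 lists passed limma's camera with a preset correlation and not with an estimated correlation (adjusted p = 0.238, 0.231 and 0.232 with an estimated correlation). Genes of lipid droplets and lipid uptake were lower in 15 of 18 members, and that list passed with either correlation. Over single genes, 28 of the 10995 tested passed limma's test at an adjusted p under 0.05, 11 of them higher and 17 lower in treated livers.

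The genes that rose included a pair of neighbouring secreted ribonucleases. Ang, which encodes angiogenin, rose from 59.6 ± 6.03 to 147 ± 34.8 FPKM, and Rnase4 rose from 332 ± 54.3 to 724 ± 123 FPKM. Their log2 fold changes were 1.25 (SE 0.16) and 1.12 (SE 0.15), each with a limma adjusted p of 0.0173. Ang (ENSMUSG00000072115, chromosome 14, 51091150 to 51102009, plus strand, GRCm38) lies within Rnase4 (ENSMUSG00000021876, chromosome 14, 51091077 to 51106151, plus strand). The genes share 18.2% of the exonic length of Ang and 13.4% of that of Rnase4 on the same strand, so the division of reads between them is uncertain. In both genes treated mouse 5_2 stood below the other treated livers.

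Wfdc21, a small secreted protein of the whey acidic protein family, rose from 587 ± 93.7 to 1279 ± 363 FPKM (chromosome 11, 83746940 to 83752642). Nnmt, which methylates nicotinamide, rose from 44.4 ± 12.1 to 110 ± 39.9 FPKM (chromosome 9, 48591877 to 48605153). Chil1, a secreted chitinase-like protein, rose from 2.29 ± 0.279 to 6.42 ± 2.52 FPKM (chromosome 1, 134182176 to 134190181). S100a9, a subunit of the calprotectin of neutrophils, rose from 7.88 ± 2.37 to 77.0 ± 85.6 FPKM (chromosome 3, 90692632 to 90695721), a log2 fold change of 2.62 (SE 0.49, limma adjusted p = 0.0449). Treated mouse 4_5 had 246.5 FPKM of S100a9 and the other treated livers 18.03 to 68.93, with a mean of 43.1 without it (log2 fold change 2.18, limma adjusted p = 0.0348). The call of S100a9 was lost without any of the 6 vehicle livers (2_1, 2_3, 2_4, 2_5, 3_2 and 6_1, limma adjusted p = 0.0945, 0.106, 0.0925, 0.0857, 0.12 and 0.0908) and without treated 5_1, 5_3 or 5_5 (limma adjusted p = 0.0676, 0.112 and 0.0982). The co-chaperone gene Dnajc12 rose from 2.08 to 4.75 FPKM and the sugar phosphate transporter gene Slc37a1 from 0.636 to 1.83 FPKM. The limma adjusted p-values of these genes lay between 0.0228 and 0.0449, and all 6 treated livers lay above the vehicle mean in each.

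Among the genes that fell were several of fat storage and lipid transport. Cidea, a protein that enlarges lipid droplets, fell from 63.7 ± 19.6 to 25.1 ± 8.19 FPKM (chromosome 18, 67343604 to 67367785, limma adjusted p = 0.0419). Mogat1, an acyltransferase of triglyceride synthesis, fell from 9.81 ± 2.38 to 4.24 ± 1.07 FPKM (chromosome 1, 78510991 to 78538173, limma adjusted p = 0.0234). Apoa4, an apolipoprotein, fell from 1999 ± 198 to 1028 ± 323 FPKM (chromosome 9, 46240696 to 46243459, limma adjusted p = 0.0426). Genes on the other strand cover 69.8% of the exons of Apoa4, and whether the counting used strand is not given in the sources used here, so its level is uncertain. Sprr1a, a small proline-rich protein, fell by 1.95 on the log2 scale (SE 0.31), from 25.6 ± 14.0 to 5.40 ± 1.79 FPKM (chromosome 3, 92483952 to 92485895). Cyp21a1 fell from 2.32 to 0.707 FPKM, Cyp2c55 from 4.83 to 2.34 FPKM and Fndc10 from 6.55 to 3.15 FPKM. Krt8-ps, a processed pseudogene whose reads may come from its parent gene, fell from 4.14 to 1.87 FPKM. All 6 treated livers lay below the vehicle mean in each of these genes. In all 28 called genes the treated livers lay on a single side of the vehicle mean. The test selects for this on the same livers, so it is no further support. By the stricter measure of groups that did not overlap, 26 of the 28 called genes qualified. Over all tested genes 127 of 10995 did, where chance gives 24.

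**Figure D1:**
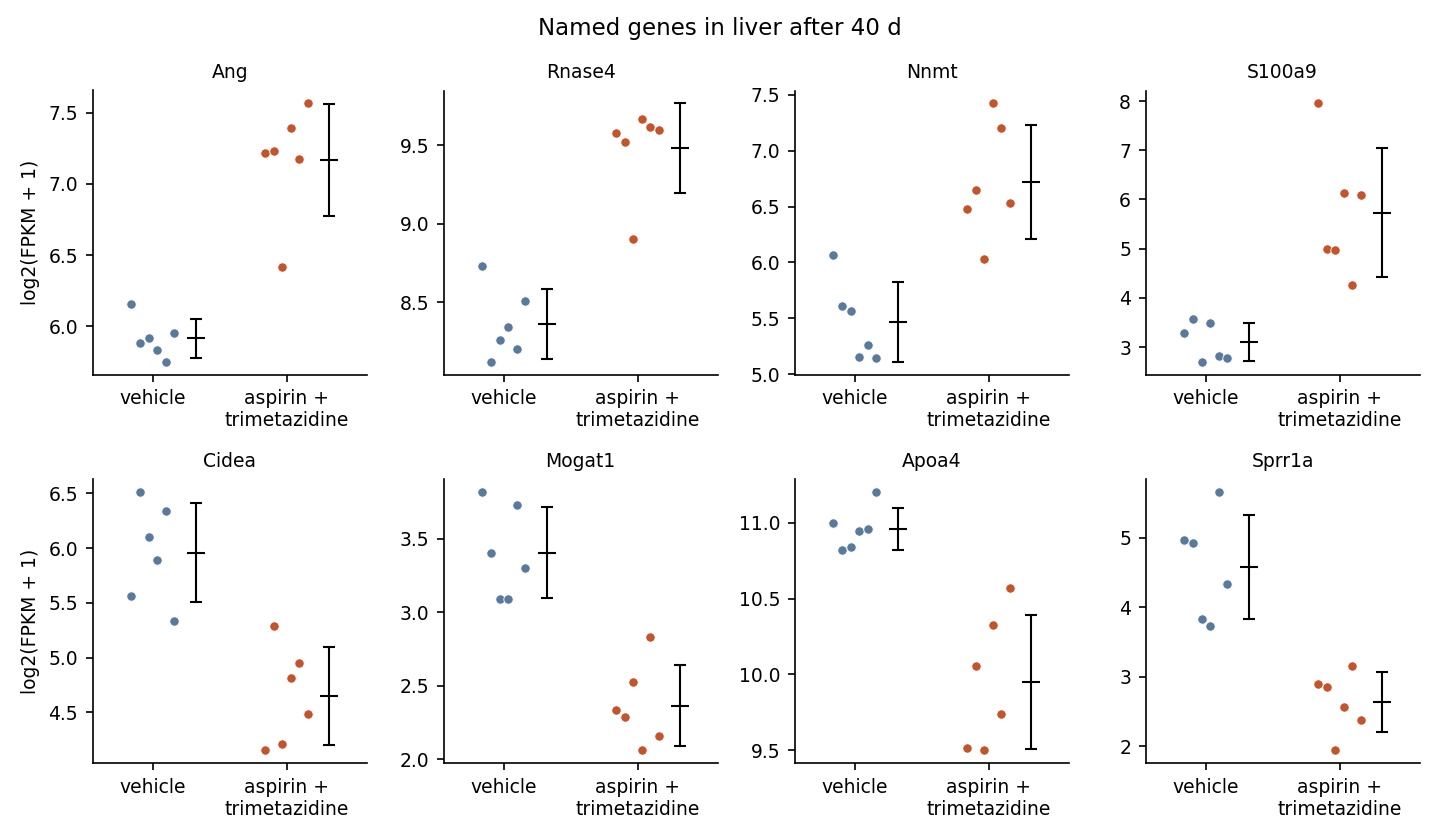
Expression of 8 named genes in liver after 40 d on the log2(FPKM + 1) scale, one point per mouse in the order of the label numbers, with the mean and SD of 6 mice beside each group. Ang, Rnase4, Nnmt and S100a9 were higher and Cidea, Mogat1, Apoa4 and Sprr1a lower in the treated livers.

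Of the 33 gene lists tested in liver with limma's camera, 20 passed at an adjusted p under 0.05, 9 higher and 11 lower. With an estimated correlation in place of the preset correlation, 1 list passed, that of lipid droplets. The adjusted p-values that follow are camera's, and the p with an estimated correlation stands beside each. An exact permutation test of the list means over the 924 relabellings of the 12 livers, two-sided and adjusted over the 33 lists, passed 6 lists, namely neutrophil, lipid droplet, prostaglandin, fatty acid synthesis, tricarboxylic acid cycle and PPARα-responsive genes.

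The acute phase list rose with an adjusted p of 2.07e-14, against an adjusted p = 0.238 with an estimated correlation. None of its 19 members passed over all genes, while 17 were higher and 1 lower adjusted over the list alone. Serum amyloid A gene Saa1 stood at 82.4 ± 16.9 FPKM in vehicle and 1171 ± 1050 in treated livers, Orm2 at 133 ± 21.4 and 1076 ± 777, and Orm1 at 1162 ± 71.4 and 3858 ± 2241. Hamp, which encodes the iron hormone hepcidin, was the 1 member that was lower (759 ± 305 against 424 ± 276 FPKM). It was named after its value was seen. By the list score, the mean log2 difference from the vehicle mean, 5 of 6 treated livers lay above every vehicle liver, between 0.99 and 2.22, while treated mouse 5_2 lay at −0.38, below every vehicle liver.

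The neutrophil list rose with an adjusted p of 6.17e-07, against an adjusted p = 0.231 with an estimated correlation. All 5 members were higher adjusted over the list alone, and S100a9 passed over all genes. Camp entered the test through the treated livers alone. With any 1 treated liver left out, including 4_5, fewer than 5 members were tested, so the list had no test there. S100a8, the partner of S100a9 in calprotectin, stood at 5.52 ± 1.11 FPKM in vehicle and 45.4 ± 56.2 in treated livers, and Camp, a granule protein, at 0.230 ± 0.158 and 5.30 ± 5.59. Without treated 4_5, the treated means of S100a8 and Camp were 22.9 and 3.14 FPKM. The scores of the treated livers ranged from 0.71 to 3.72, with treated mouse 4_5 highest. The exact permutation p of 0.00217 was the smallest that 6 against 6 livers can give. Red cell transcripts, a sign of blood in the tissue, also rose as a list, with all 5 members higher by a median of 0.68 (adjusted p = 0.0209, and adjusted p = 0.532 with an estimated correlation). Hbb-bs stood at 427 ± 197 and 796 ± 411 FPKM. The red cell call was lost without vehicle 3_2 or 6_1 or treated 5_1, 5_2 or 5_4 (adjusted p = 0.0673, 0.0808, 0.0503, 0.0916 and 0.103).

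Lists of inflammation, macrophages and matrix were higher by smaller amounts. The list of inflammatory cytokines and NF-κB targets rose by a median of 0.21, with 18 of 20 members positive (adjusted p = 0.000204, and adjusted p = 0.508 with an estimated correlation). Icam1 stood at 5.22 ± 0.533 and 7.96 ± 2.76 FPKM. Antigen presentation rose by a median of 0.22, with 14 of 15 members positive (adjusted p = 0.000684, and adjusted p = 0.532 with an estimated correlation). The Kupffer cell list rose by a median of 0.27, with 8 of 8 members positive (adjusted p = 0.0136, and adjusted p = 0.532 with an estimated correlation). Treated mouse 4_5 had a Kupffer cell score of 1.69 and the other treated livers scores of −0.13 to 0.34, and without it the call was lost (adjusted p = 0.153). Without 4_5 the mean difference in score went from 0.38 to 0.12 for Kupffer cells and from 0.28 to 0.16 for cytokines and NF-κB targets. The extracellular matrix list rose by a median of 0.18, with 23 of 30 members positive (adjusted p = 0.0136, and adjusted p = 0.681 with an estimated correlation). This call was lost without vehicle 2_3 or treated 5_1 or 5_5 (adjusted p = 0.153, 0.127 and 0.285), where the mean score difference of 0.19 became 0.12, 0.12 and 0.06. No member of these 4 lists passed over all genes or adjusted over the list alone.

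The list of the unfolded protein and integrated stress response rose by a median of 0.34, with 19 of 22 members positive (adjusted p = 4.48e-05, and adjusted p = 0.527 with an estimated correlation). No member passed over all genes and 1 was higher adjusted over the list alone. Asns, the asparagine synthetase gene, stood at 0.913 ± 0.334 and 4.15 ± 2.90 FPKM, and Chac1, which degrades glutathione, at 1.88 ± 0.470 and 5.53 ± 3.46. The prostaglandin pathway list, which holds the targets of aspirin, rose with an adjusted p of 0.00268, against an adjusted p = 0.118 with an estimated correlation. Its 8 measured members had a median log2 fold change of 0.13 and a mean of 0.28, 7 were positive, and 2 were higher adjusted over the list alone. Alox5ap, of leukotriene synthesis, stood at 2.09 ± 0.346 and 4.21 ± 1.56 FPKM, Ptgis, the prostacyclin synthase gene, at 3.29 ± 0.852 and 5.89 ± 1.95, and Ptgs1 at 5.23 ± 0.908 and 8.04 ± 4.01. Treated 4_5 had 16.09 FPKM of Ptgs1, and without it the treated mean was 6.44. All 6 treated list scores lay above every vehicle score.

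The list of fatty acid synthesis fell, with an adjusted p of 4.82e-11, against an adjusted p = 0.232 with an estimated correlation. No member passed over all genes, and 15 of 21 were lower adjusted over the list alone. Fasn, the fatty acid synthase gene, stood at 126 ± 44.8 FPKM in vehicle and 62.9 ± 22.8 in treated livers, Pklr, the liver pyruvate kinase gene, at 136 ± 37.4 and 77.3 ± 25.1, and Acacb, an acetyl-CoA carboxylase gene, at 21.0 ± 3.96 and 12.6 ± 4.96. The lipid droplet and lipid uptake list fell by a median of 0.28 on the log2 scale, with an adjusted p of 1.05e-06, and with an estimated correlation the adjusted p was 0.00715. Cidea and Mogat1 passed over all genes and 6 members were lower adjusted over the list alone. Plin2, which coats lipid droplets, stood at 350 ± 69.7 and 218 ± 31.5 FPKM, and Cidec at 160 ± 24.0 and 95.0 ± 28.3. Cholesterol synthesis fell as a list, with 21 of 23 members negative and a median of −0.30 (adjusted p = 1.08e-06, and adjusted p = 0.329 with an estimated correlation), and 2 members were lower adjusted over the list alone. Gluconeogenesis and glucose handling fell, with 14 of 16 members negative and a median of −0.32 (adjusted p = 0.000199, and adjusted p = 0.319 with an estimated correlation).

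Lists of mitochondrial fuel use also fell. All 19 members of the tricarboxylic acid cycle list were negative, with a median of −0.23 (adjusted p = 6.49e-09, and adjusted p = 0.299 with an estimated correlation), and 8 were lower adjusted over the list alone. Dlat, of the pyruvate dehydrogenase complex, stood at 23.8 ± 5.04 and 15.9 ± 4.07 FPKM. Fatty acid oxidation had 22 of 24 members negative and a median of −0.18 (adjusted p = 6.17e-07, and adjusted p = 0.329 with an estimated correlation), and 2 were lower adjusted over the list alone. Decr1, of the oxidation of unsaturated fatty acids, stood at 84.1 ± 4.46 and 65.6 ± 5.45 FPKM. The thiolase genes that trimetazidine addresses stood at 626 ± 61.6 and 574 ± 64.2 FPKM (Acaa2, limma adjusted p = 0.627) and at 38.6 ± 3.14 and 33.0 ± 2.67 FPKM (Hadhb, limma adjusted p = 0.237, lower in 6 of 6 treated livers). PPARα-responsive genes had a median of −0.23, with 18 of 21 members negative (adjusted p = 0.000204, and adjusted p = 0.231 with an estimated correlation), and 4 were lower adjusted over the list alone. The mitochondrial genome list fell by a median of 0.30 on the log2 scale, with 11 of 13 members negative (adjusted p = 0.000384, and adjusted p = 0.319 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of −0.08, with 44 of 54 members negative (adjusted p = 0.00857, and adjusted p = 0.784 with an estimated correlation). The mean score difference of this last list, −0.09, was −0.14 without vehicle 2_1 or treated 5_3, −0.05 without vehicle 2_3 and −0.01 without treated 5_5. Its call was lost without vehicle 2_3 or treated 5_5 (adjusted p = 0.174 and 0.746), and without treated mice 4_5 and 5_5 together the list changed direction and did not pass (adjusted p = 0.6657).

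**Figure D2:**
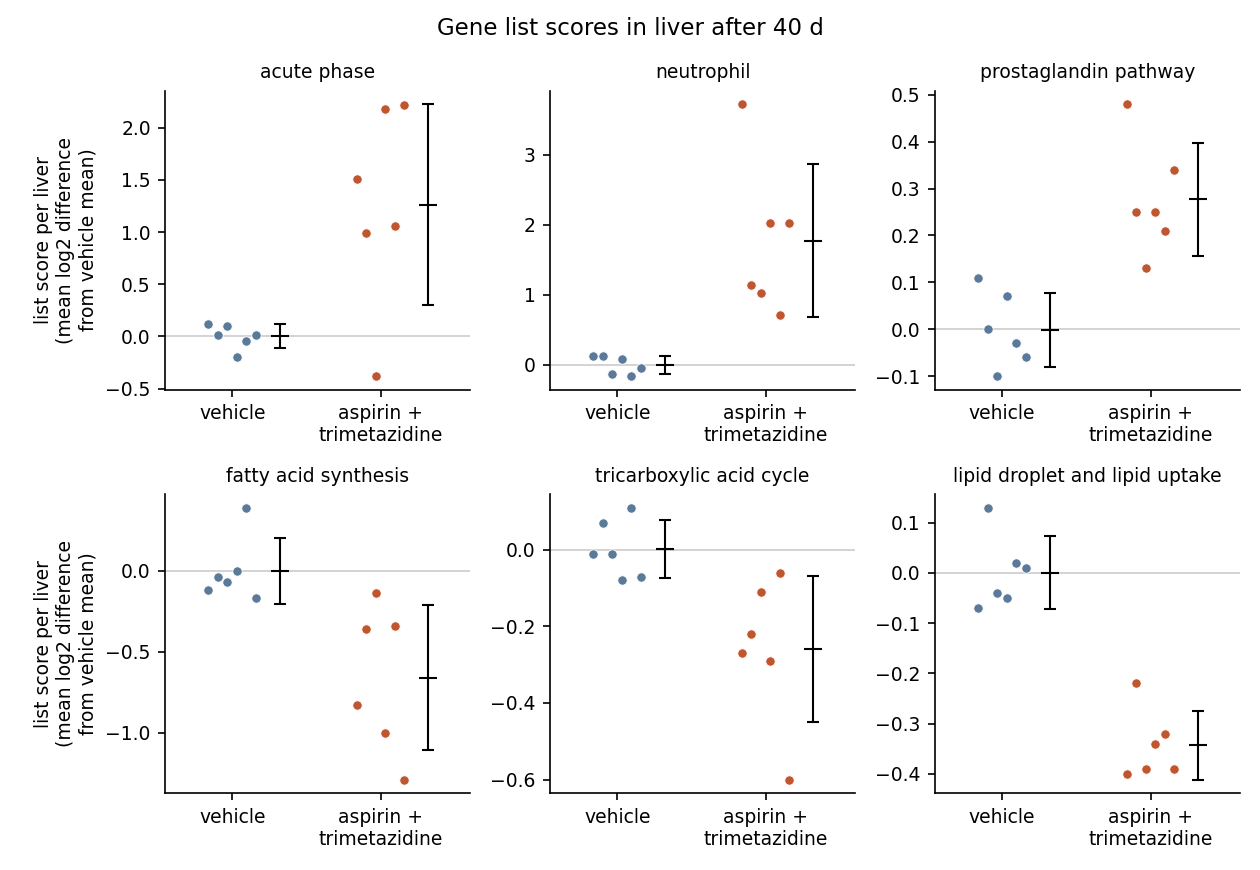
Scores of 6 gene lists in liver after 40 d, one point per mouse in the order of the label numbers, as the mean over list members of the log2(FPKM + 1) difference from the vehicle mean, with the mean and SD of 6 mice beside each group. Scores of the neutrophil, prostaglandin and lipid droplet lists did not overlap between groups, and treated mouse 5_2 had an acute phase score of −0.38.

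The cell cycle list fell by a median of 0.17 on the log2 scale, with 13 of 15 members negative (adjusted p = 0.0224, and adjusted p = 0.650 with an estimated correlation). Ccnd1, which encodes cyclin D, stood at 19.5 ± 3.28 and 11.1 ± 4.83 FPKM. The NRF2 oxidative stress list also had a median of −0.17, with 17 of 22 members negative (adjusted p = 0.0308, and adjusted p = 0.650 with an estimated correlation). Gsta1, a glutathione transferase gene, stood at 54.2 ± 23.5 and 21.4 ± 12.4 FPKM. The mean score difference of the cell cycle list, −0.23, was −0.36 without treated 4_5 and −0.14 without treated 5_5, and that of the NRF2 list, −0.28, was −0.15 without treated 5_5. The cell cycle call was lost without vehicle 2_1 or treated 5_3 or 5_5 (adjusted p = 0.0591, 0.139 and 0.234). The NRF2 call was lost without vehicle 2_1, 2_3 or 3_2 or treated 5_1, 5_3 or 5_5 (adjusted p = 0.0563, 0.0671, 0.105, 0.0608, 0.0936 and 0.187). The other 13 lists had adjusted p-values between 0.132 and 0.946. In the list of drug-metabolising cytochromes (adjusted p = 0.132) members moved both ways, 3 higher and 4 lower adjusted over the list alone. For the insulin signalling and bile acid lists, the median and the test had opposite signs.

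Several genes of interest did not pass the test in liver. Fgf21, a hormone of the fasting liver, stood at 24.6 ± 9.31 and 37.2 ± 33.1 FPKM (limma adjusted p = 0.747), with a treated mean of 23.9 without treated 5_3, and Gdf15, a stress cytokine, at 9.999 ± 2.06 and 9.28 ± 4.26 (limma adjusted p = 0.784). The collagen gene Col1a1 stood at 9.87 ± 4.78 and 16.4 ± 15.5 FPKM (limma adjusted p = 0.860), the metalloproteinase inhibitor gene Timp1 at 6.91 ± 2.10 and 13.6 ± 8.46 (limma adjusted p = 0.325), and the macrophage gene Adgre1 at 13.4 ± 1.22 and 32.1 ± 39.2 (limma adjusted p = 0.482), the last with a treated mean of 16.1 without treated 4_5. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 35.1 ± 14.9 and 47.7 ± 14.0 FPKM (limma adjusted p = 0.431), and Cpt1a, which admits fatty acids to mitochondria, at 153 ± 17.4 and 124 ± 20.2 (limma adjusted p = 0.265). Ppargc1a, Tnf and Ptgs2 lay below the filter on low values, at means of 1.11 and 1.22, 0.516 and 0.567, and 0.0403 and 0.0784 FPKM.

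The count of 28 genes rested on small margins, and so did single calls besides that of S100a9. In alternative settings, fits without 1 liver among them, the call of Cyp2c55 held in 5 of 22 and that of Krt8-ps in 6 of 22. Those of Nnmt and S100a9 held in 8 of 23 each, those of Apoa4 and Cidea in 9 of 23, and those of Ang and Rnase4 in 16 of 23. Leaving out 1 liver at a time gave between 0 and 83 genes, 0 without vehicle 2_3 or treated 5_3, 1 without vehicle 3_2, 2 without vehicle 2_1, 8 without vehicle 2_5, 13 without treated 5_5, 15 without vehicle 2_4 or vehicle 6_1, 16 without treated 5_4, 17 without treated 5_1, and 83 without treated 5_2. No gene passed when low genes were kept, when livers 4_5 and 5_5 were omitted, among label numbers 2 and 5 alone, or by an exact Wilcoxon test, although 127 genes against 24 expected by chance reached the smallest p of that test.

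The second comparison asked the same of muscle. No muscle gene passed limma's test among 11708 tested, where 451 had an unadjusted p under 0.05 and chance gives 585. Limma voom on the recovered reads gave 0 genes, with 440 at an unadjusted p under 0.05. An exact Wilcoxon test also gave 0, with 429, but its smallest possible p of 0.00217 could hardly pass a gene. Limma gave 1043 such genes with array weights, 913 without muscles 5_5 and 6_1, 749 without treated 5_5 and 712 among label numbers 2 and 5. Of these fits only array weights called a gene, 1 in all. Leaving out any other single muscle gave 333 to 616. As lists, fatty acid oxidation was lower in 25 of 25 members with a median of −0.24, the tricarboxylic acid cycle in 19 of 19 with a median of −0.18, fatty acid synthesis in 18 of 20 with a median of −0.31, and extracellular matrix in 27 of 33 with a median of −0.22. The mean score difference went from −0.24 to −0.16 for fatty acid oxidation and from −0.19 to −0.11 for the tricarboxylic acid cycle without vehicle 6_1, and from −0.16 to −0.11 for matrix without treated 5_2. Red cell transcripts were higher in 5 of 5 members by a median of 0.90. These 5 lists passed only with camera's preset correlation (adjusted p = 0.565, 0.803, 0.565, 0.619 and 0.565 with an estimated correlation).

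Of 30 lists tested in muscle, 8 passed camera with the preset correlation and 0 did with an estimated correlation, by fry or by exact permutation, which had 1, 0 and 1 lists at an unadjusted p under 0.05. The adjusted p was 7.22e-11 for fatty acid oxidation (adjusted p = 0.565 with an estimated correlation), and 4.12e-07 for extracellular matrix, the tricarboxylic acid cycle and fatty acid synthesis (adjusted p = 0.619, 0.803 and 0.565 with an estimated correlation). It was 7.04e-05 for red cells and 8.86e-05 for the mitochondrial genome (adjusted p = 0.565 and 0.694 with an estimated correlation). For nuclear oxidative phosphorylation and cholesterol synthesis it was 0.0184 and 0.0199 (adjusted p = 0.957 and 0.898 with an estimated correlation), with medians of −0.08 and −0.09. Adjusted over the list alone, 4 matrix genes, 2 mitochondrial genes and 1 gene of fatty acid synthesis were lower, and no member passed over all genes. The oxidative phosphorylation list changed direction among label numbers 2 and 5 alone (adjusted p = 0.0007595) and without vehicle 6_1 (adjusted p = 0.4156). Its call was also lost without vehicle 3_2 or treated 4_5, 5_1, 5_3 or 5_4 (adjusted p = 0.0932, 0.294, 0.196, 0.281 and 0.0984), and that of cholesterol synthesis without vehicle 2_3 or treated 4_5 or 5_2 (adjusted p = 0.301, 0.075 and 0.183). The mean score difference of oxidative phosphorylation, −0.08, was −0.13 to −0.15 without vehicle 2_1 or 2_3 or treated 5_2 or 5_5, −0.04, −0.05 and −0.04 without treated 4_5, 5_1 and 5_3, and 0.04 without vehicle 6_1. That of cholesterol synthesis, −0.10, was −0.16 without vehicle 6_1 or treated 5_5 and −0.04 without vehicle 2_3.

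Values of single members show the sizes. In vehicle and treated muscle, Acsl1, which activates fatty acids, stood at 63.9 ± 7.87 and 49.3 ± 7.34 FPKM, the thiolase gene Acaa2 at 191 ± 57.0 and 144 ± 35.3, and Hadhb at 58.7 ± 13.7 and 46.2 ± 8.42. Col6a2 stood at 18.9 ± 1.85 and 13.5 ± 1.55 FPKM and Col3a1, another collagen gene, at 50.8 ± 10.5 and 34.0 ± 6.57, lower in 6 of 6 treated muscles. Acss2, which makes acetyl-CoA from acetate, stood at 9.23 ± 1.54 and 6.15 ± 1.07 FPKM, and Fasn at 73.0 ± 23.2 and 42.6 ± 12.4. S100a9 stood at 3.11 ± 2.24 and 15.5 ± 10.4 FPKM, higher in 6 of 6 treated muscles (limma adjusted p = 0.778). The smallest limma adjusted p, 0.0958, belonged to the pseudogene Gm3362 (12.9 ± 2.16 and 22.7 ± 2.51 FPKM). It was followed by AC123870.1 at 0.191. Pcca, of propionate breakdown, Tnfrsf4, mt-Atp8 and Borcs7 were among the genes at 0.778, as were Col6a2, S100a9 and Acss2. The mitochondrial genes mt-Atp8 (13.2 ± 7.28 and 4.58 ± 1.89 FPKM) and mt-Co2 (445 ± 178 and 211 ± 61.5) have close nuclear copies and are uncertain.

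Genes of exercise, fuel choice and fibre type did not pass the test. Ppargc1a, a coactivator of mitochondrial biogenesis, stood at 5.40 ± 1.62 and 4.31 ± 1.35 FPKM, the glucose transporter gene Slc2a4 at 196 ± 18.9 and 202 ± 34.3, Pdk4, which restrains glucose oxidation, at 242 ± 176 and 189 ± 216, and Ucp3 at 63.7 ± 46.3 and 49.5 ± 47.1. Without treated 4_5, the treated means of Pdk4 and Ucp3 were 106.5 and 31.95 FPKM. The slow myosin gene Myh7 stood at 59.2 ± 55.6 and 50.3 ± 46.0 FPKM, the fast myosin gene Myh4 at 4945 ± 532 and 5125 ± 1029, and Ptgs1 at 2.88 ± 0.473 and 2.90 ± 0.428. All of these had a limma adjusted p of 0.999. Cpt1b shares 81.4% of its exons with another gene on the same strand, and its 0.993 and 0.910 FPKM are uncertain. Fgf21, Gdf15, Ptgs2 and Fbxo32 lay below the filter. Fbxo32, a ubiquitin ligase gene of muscle atrophy, was listed at means of 0.00375 and 0.00766 FPKM. Whether its reads were counted in full is uncertain, so these values do not show that the gene was silent. The acute exercise list had an adjusted p of 0.973, slow-twitch and fast-twitch fibre 0.4998 each, glycolysis 0.549, adipocyte 0.594 and mitochondrial biogenesis 0.907. The 22 lists that did not pass lay between 0.0873 and 0.973. Treated muscle 5_5 and vehicle muscle 6_1 stood apart on the first principal components, at 45.3 on the first and −32.4 on the second.

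The third comparison tested whether the treatment effect differed between the tissues. Rnase4 was the 1 gene of 9436 that passed limma's test of the difference. It rose in liver by 1.12 on the log2 scale and had −0.14 in muscle, a difference, muscle minus liver, of −1.26 (SE 0.20, limma adjusted p = 0.0112). The next genes had limma adjusted p-values of 0.131 to 0.143, among them Ang with −1.18, Dnajc12 with −0.89, 6030419C18Rik with 1.05, Palmd with 0.54 and Asrgl1 with 0.52. At an unadjusted p under 0.05 there were 492 genes, where chance gives 472. Across genes, which are not independent replicates, the effects in the tissues had a Spearman rho of 0.22. Of the 28 genes called in liver, 15 were measured in muscle and 9 of these had the same sign there. The call of Rnase4 was lost, leaving 0 genes, without treated mouse 5_3, 5_4 or 5_5. Without vehicle 2_4 or 6_1 or treated 4_5, 5_1 or 5_2, 2 genes passed. The main fit did not pair liver and muscle by label number. With the number as a fixed block 3 genes passed, Rnase4 among them. The opposite directions of the matrix list in liver and muscle were not tested against each other.

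The fourth comparison looked at the liver 24 h after treatment, in 1 treated and 1 vehicle liver, so no value below has a replicate check. The acute phase list was higher in all 19 members of the treated liver, by a median of 0.66, at the top of 10000 random lists of like expression (percentile 100). Hamp was at 167 FPKM in the vehicle and 897 in the treated liver, and Saa1 at 117 and 278. The chemokine gene Cxcl1 was at 6.42 and 31.4 FPKM and the metallothionein gene Mt2 at 4.72 and 46.4, with 73.5% of the exons of Mt2 covered by a gene on the other strand. Fatty acid synthesis was also higher, by a median of 0.39 (percentile 100), with Fasn at 55.5 and 80.1 FPKM. This is the opposite sign to 40 d.

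In all, 85 of 6825 genes with a mean of at least 5 FPKM differed by 2-fold or more between the livers, 53 higher and 32 lower in the treated liver. The largest ratios also included Coro1b (1.85 and 13.4 FPKM) and the immunoglobulin gene Igkv6-17 (15 and 74 reads). Lower in the treated liver were Rps27rt (482 and 142 FPKM), the ribosomal RNA gene CT010467.1 (1055 and 315), Lars2 (30.0 and 8.30), Igfbp6 (9.82 and 2.68), Fhl2 (16.5 and 6.21) and Trbd1, which had 3 reads in the vehicle and 0 in the treated library. CT010467.1 shares 73.9% of its exons with genes on the other strand, Rps27rt is a retrotransposed copy of a ribosomal protein gene, and both are uncertain. Lars2 had the same log2 ratio as the ribosomal RNA gene CT010467.1, −1.74, so its value is uncertain too. Whether Lars2 itself fell was not tested. Cyp7a1 was at 52.4 and 22.4 FPKM, Fgf21 at 38.3 and 26.9, Cpt1a at 180 and 239, Acaa2 at 564 and 705, and Hadhb at 37.0 and 43.0. Ptgs1 was at 4.22 and 5.14 FPKM, Timp1 at 10.6 and 12.2, Col1a1 at 19.4 and 15.3, and Adgre1 at 19.2 and 15.5. Gluconeogenesis (median 0.39, percentile 99.99), the unfolded protein and integrated stress response (0.25, 99.89) and lipid droplets (0.25, 99.65) lay high among random lists. Extracellular matrix (−0.26, percentile 0), red cells (−0.75, percentile 0) and drug-metabolising cytochromes (−0.27, percentile 0) lay low. All 24 members of fatty acid oxidation were higher, by a median of 0.25 (percentile 96.75). Lists of cell types also differed between these livers: hepatocyte genes were higher in 13 of 14 members (median 0.31, percentile 98.14) and Kupffer cell genes in 7 of 8 (0.26, 97.69), while cholangiocyte genes were lower in 9 of 9 (−0.24, 0.14) and those of recruited macrophages in 11 of 19 (−0.05, 0.22). Whether a different mix of cells accounts for the other lists was not tested. Of the 33 liver lists at 24 h, 7 lay at percentile 97.69 or above and 8 at 1.92 or below. The random lists matched size and mean expression but not the correlation within a list. An extreme percentile is therefore not a test of treatment.

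Many of the largest differences in muscle at 24 h were in genes that mark other cells and tissues, in 1 treated against 1 vehicle library. Immunoglobulin transcripts were abundant in the treated muscle, with Igkc at 9.07 FPKM in the vehicle and 308 in the treated library, Igkv3-5 at 4 and 241 reads, and Igkv4-70, Ighv1-72, Igkv8-30 and Igkj2 at 0 reads in the vehicle and 209, 141, 109 and 10 in the treated library. Transcripts of liver proteins were present in the vehicle muscle, with Apoa2 at 341 and 2 reads, Apoa1 at 417 and 1, Ttr at 297 and 0, Gc at 294 and 0, and Fabp1 at 142 and 1. Of transcripts that averaged under 5 FPKM in muscle at 40 d, the 30 most abundant in the vehicle liver stood in the vehicle muscle at a median of 0.404% of their level in the vehicle liver. The adipocyte list was higher in all 14 members of the treated muscle by a median of 1.11, and slow-twitch fibre genes in all 9 by a median of 0.86. Fast-twitch fibre genes were lower in 11 of 13 members, with a median of −0.76.

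A 2-fold difference or more was present in 215 of 6763 muscle genes, 159 higher and 56 lower in the treated library. Fatty acid oxidation (median 0.65, 24 of 24 members higher), fatty acid synthesis (0.76), PPARα-responsive genes (0.60), cholesterol synthesis (0.42) and the acute exercise list (0.51) reached percentile 100 of random lists, and the mitochondrial genome (0.64) and heat shock (0.36, 13 of 15 members higher) percentile 99.95. Antigen presentation (0.36, 15 of 15, percentile 99.91), the unfolded protein response (0.21, 99.85), nuclear oxidative phosphorylation (0.14, 99.80) and nerve and Schwann cell genes (0.36, 7 of 9, 99.75) also lay high. Glycolysis (−0.51) and fast-twitch fibre lay at percentile 0, denervation (−0.38) at 0.17 and circadian clock (−0.25) at 0.48. Extreme percentiles were thus common in this pair of libraries: of 31 muscle lists, 16 lay at percentile 97.91 or above and 4 at 0.48 or below. A high or low percentile alone does not single out a list here. Acaa2 was at 134 and 226 FPKM, Hadhb at 44.1 and 81.4, Pdk4 at 170 and 255, Ucp3 at 66.6 and 68.3, Slc2a4 at 205 and 146, Myh4 at 6230 and 3289, and Ppargc1a at 3.11 and 3.55. Gapdh was at 112 and 3.74 FPKM, but it has many pseudogene copies and its values are uncertain. Mitochondrial reads made up 6.94% of reads on genes in the vehicle and 10.97% in the treated library.

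The fifth comparison set 24 h beside 40 d. Across genes, which are not independent replicates, the log2 ratios at 24 h and 40 d had a Spearman rho of −0.05 in liver and −0.10 in muscle. Of the 28 genes called in liver at 40 d, 17 (60.7%) had the same sign at 24 h, 10 of the 11 higher and 7 of the 17 lower ones. The ratios at 24 h were positive for 61.3% and negative for 38.2% of all tested liver genes, shares that alone give 6.7 of 11 and 6.5 of 17, or 13.2 of 28. Nnmt was already higher at 24 h, at 20.6 FPKM in the vehicle and 57.8 in the treated liver, while Cidea, lower at 40 d, was at 13.1 and 28.9. Of the 20 lists called in liver at 40 d, 7 had the same sign at 24 h, acute phase and the unfolded protein response among them. Ratios in the liver pair at 24 h leaned positive, with a median of 0.092 over genes with a mean of at least 5 FPKM. This lean favours the same sign for lists higher at 40 d, and the count of 7 was not set against it. Of the 8 lists called in muscle, 0 had the same sign at 24 h. With 1 library per group at 24 h the difference between the times was not tested. In muscle, Myh7 stood at 0.0663 FPKM in the vehicle and 0.139 in the treated library at 24 h, far below its level at 40 d. The muscles at 24 h and 40 d may thus be unlike pieces, and the vehicle muscle at 24 h held liver transcripts. The unlike signs in muscle therefore do not show an effect of time.

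**Figure D3:**
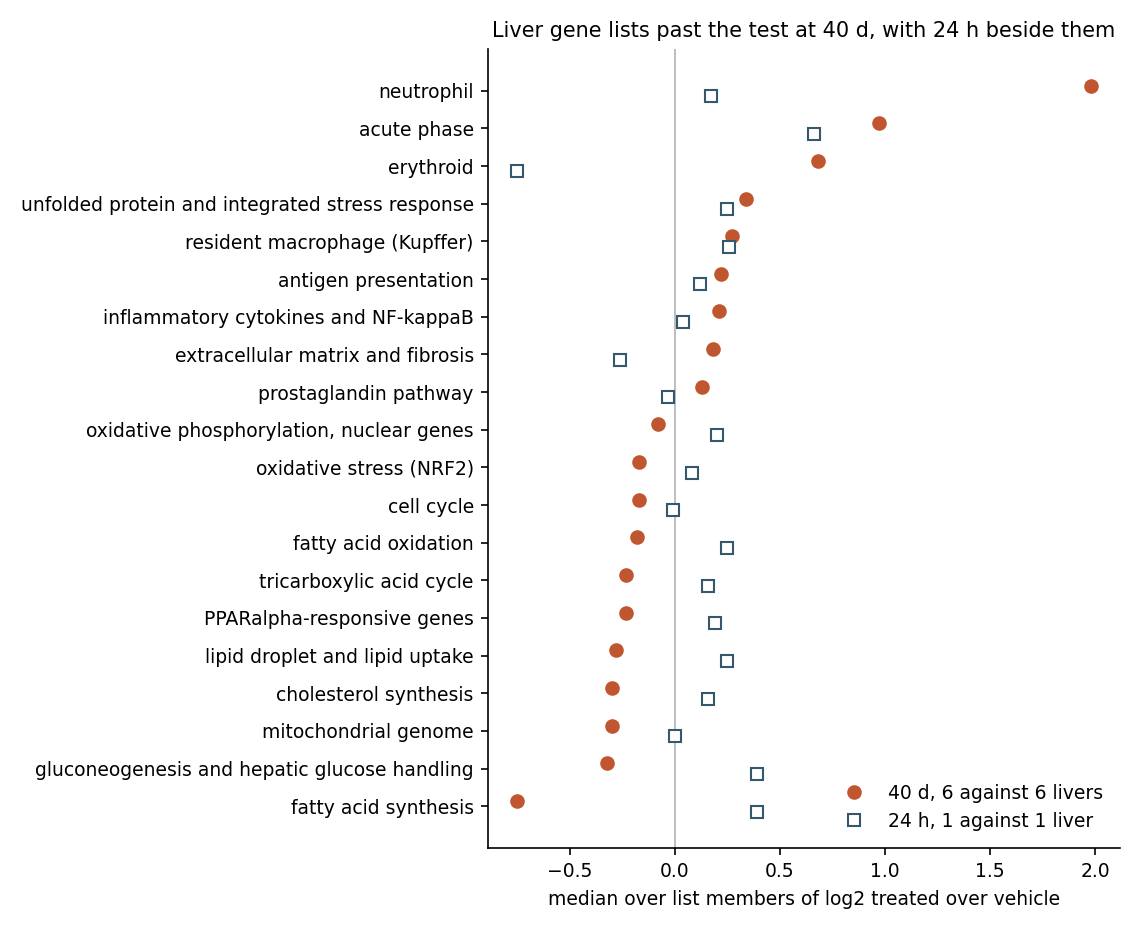
Median log2 ratio of treated over vehicle for the 20 gene lists that passed the camera test in liver at 40 d, with filled circles for 40 d (6 against 6 livers) and open squares for 24 h (1 against 1 liver, no error). Acute phase was higher at both times (0.97 and 0.66), while fatty acid synthesis was lower at 40 d (−0.75) and higher at 24 h (0.39).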

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

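All of the values in this part come from tests set before the results were seen: within each group of 6, the gap between the highest or lowest library and its neighbour was divided by the range and compared with Dixon's 95% limit. Of 298 groups of values tested, 22 passed the limit, where chance gives 15. Levels below are list scores or log2(FPKM + 1).

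In liver, vehicle mouse 3_2 stood highest of its group in the fatty acid synthesis list (score 0.39 against −0.17 to 0, gap over range 0.70), the gluconeogenesis list (0.22 against −0.07 to −0.02, 0.82) and Dlat (5.12 against 4.42 to 4.64, 0.69). Vehicle mouse 2_1 stood highest in Rrm2 (3.04 against 2.51 to 2.68, 0.68) and lowest in Saa1 (5.73 against 6.41 to 6.72, 0.69). Treated mouse 4_5 stood highest in the Kupffer cell list (1.69 against −0.13 to 0.34, 0.74) and in the macrophage genes Cd5l (9.44 against 7.54 to 8.10, 0.71), Vsig4 (6.75 against 5.46 to 5.87, 0.68) and Adgre1 (6.82 against 3.95 to 4.24, 0.90). It also stood highest in Ptgs1 (4.09 against 2.62 to 3.05, 0.71). Treated mouse 5_2 stood lowest in Ang (6.42 against 7.17 to 7.57, 0.66) and Rnase4 (8.91 against 9.52 to 9.67, 0.81). Treated mouse 5_5 stood lowest in the oxidative phosphorylation list (−0.51 against −0.10 to 0.14, 0.63).

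In muscle, vehicle mouse 6_1 stood lowest in the fatty acid synthesis list (−0.61 against 0.04 to 0.33, 0.69), Fasn (4.85 against 6.25 to 6.59, 0.81) and Cyp51 (1.75 against 2.25 to 2.52, 0.65). Treated mouse 5_2 stood highest in the tricarboxylic acid cycle list (0.20 against −0.34 to −0.19, 0.73), Cyc1 (8.07 against 7.40 to 7.58, 0.74) and Fh1 (6.52 against 6.01 to 6.13, 0.77). Treated mouse 5_1 stood highest in mt-Atp6 (9.44 against 6.97 to 7.78, 0.67). Treated mouse 5_5 stood lowest in Ppargc1a (1.49 against 2.35 to 2.72, 0.70) and Slc2a4 (7.12 against 7.65 to 7.89, 0.68).

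Rnase4 was singled out by limma's test of the difference between tissues, with a log2 effect of 1.12 in liver and −0.14 in muscle and a difference of −1.26.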

How the results depend on the processing

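Limma voom on the recovered reads, FPKM per total reads, the omission of livers 4_5 and 5_5 or of muscles 5_5 and 6_1 together, and median-of-ratios scaling for the share at 24 h were chosen after seeing the data. The planned count tests on recovered reads were not run, and voom took their place. Where no reason is given, the cause was not tested.

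The 28 liver genes became 25 with a pseudocount of 0.1, 19 with the stricter filter, 28 with median-of-ratios scaling, 36 with quantile scaling, 38 with array weights (19 higher and 19 lower, against 11 and 17), 29 with voom (24 of them shared) and 23 per total reads. They became 0 with no filter on low values, where 26705 genes were tested, 0 among label numbers 2 and 5 alone, where fewer mice were compared, 0 by the Wilcoxon test, whose smallest p of 0.00217 gave no adjusted p under 0.187, and 0 without 4_5 and 5_5 together. Unadjusted limma p-values under 0.05 numbered 2310, 984 and 1187 in these fits and 1186 by Wilcoxon. In the main limma fit they numbered 1455, where chance gives 550. Leaving out 1 mouse gave 0 (vehicle 2_3) to 83 (treated 5_2). The 20 liver lists became 1 with an estimated correlation, 8 by fry and 6 by exact permutation, and otherwise 15 to 21. Leaving out 1 mouse gave 15 (treated 5_5) to 20.

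The 0 muscle genes became 1 with the stricter filter, 1 with quantile scaling, 1 with array weights, 1 per total reads and, leaving out 1 mouse, 0 to 1 (vehicle 6_1). The 8 muscle lists became 0 with an estimated correlation, 0 by fry and 0 by exact permutation, and otherwise 7 to 12. Leaving out 1 mouse gave 7 (treated 5_3) to 10 (treated 4_5).

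The oxidative phosphorylation list reversed in liver without 4_5 and 5_5 (adjusted p = 0.6657), and in muscle among label numbers 2 and 5 (adjusted p = 0.0007595) and without vehicle 6_1 (adjusted p = 0.4156). Leaving out 1 muscle at a time gave this list adjusted p-values of 2.534e-05 (without vehicle 2_3) to 0.4156. No other list or named gene at 40 d changed direction with a call in either setting. Genes never called did change sign, such as Col1a1 in liver (−0.09 to 0.6) and Myh7 in muscle (−0.68 to 0.32).

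Liver and muscle share label numbers, so the difference between tissues was also fitted with the number as a block, which gave 3 genes in place of 1, and 1 with the consensus correlation of 0.07. Deviations of same-numbered libraries correlated at −0.08 to 0.45, above 0.1 in 7 of 12 numbers, and 7 of 12 livers correlated best with their own number. This is a hint from the data that a number marks 1 mouse, but not every pair was above 0.1, and the labels do not say so. The main fit assumed no pairing. The other splits and the fits of this difference without 1 mouse did move the liver and muscle of a number together. Leaving out 1 mouse gave 0 (treated 5_3, 5_4 or 5_5) to 2.

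At 24 h, genes with a 2-fold difference numbered 95 and 85 in liver and 258 and 216 in muscle with a pseudocount of 0.1 and with median-of-ratios scaling, and 60.7% of called liver genes had the same sign in each. Depth limits low genes, and without replicates at 24 h no stability can be judged.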

Other observations

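The tests of other splits were set before the results were seen, and the tests of blood, label numbers, displaced reads, coupling, carried-over RNA and pieces of muscle were chosen after.

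The treated livers differed from each other in which immune signal they carried. Treated mouse 5_2 had the lowest acute phase score of the 12 livers, −0.38, and its fatty acid synthesis score of −0.14 lay among those of the vehicle livers, while its neutrophil score of 1.02 lay above all of them. It also had a cholangiocyte score of 1.51, where the other livers lay between −0.47 and 0.37. Treated mouse 4_5 had a neutrophil score of 3.72 and a Kupffer cell score of 1.69. It stood at −33.3 on the second principal component of the livers, where the others lay between −3.3 and 12.6. On the first, treated 5_2 stood at −11.4, among the vehicle livers (−16.9 to −6.5). In muscle, the neutrophil list had too few measured members for a test, and S100a9 stood at 3.11 ± 2.24 FPKM in vehicle and 15.5 ± 10.4 in treated mice.

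Other splits of the 12 mice into 6 and 6 were fitted in the same way, 100 of them with the real one. In liver 1 of 100, the real one, gave as many as 28 genes, and the highest other gave 3. Chance is thus unlikely to give that count, but not every possible split was fitted. For the 20 liver lists, 5 of 100 did, exactly the bound set for it, and the highest other gave 22, so chance cannot be excluded. In muscle every split, 100 of 100, reaches a count of 0 genes, so that count decides nothing, and the highest other gave 8. For the 8 muscle lists 60 of 100 did, with up to 21, so chance cannot be excluded. Correlation within lists could give such counts: it was estimated at 0.3 to 0.83 in the 8 muscle lists, against the preset 0.01, and camera with the estimated correlation passed 0 muscle lists and 1 liver list. A further structure of the samples was not tested. For the difference between tissues 9 of 100 gave at least 1 gene, with up to 3, so chance cannot be excluded for that count either.

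The first pattern is the higher neutrophil and acute phase lists in treated livers. More blood in these livers could raise both, since red cell transcripts were higher too. After the linear relation to the red cell score was removed, the neutrophil difference went from 1.77 to 1.69 (exact permutation p = 0.002165, the smallest that 6 against 6 can give). The acute phase difference went from 1.26 to 1.31 (exact permutation p = 0.01515). Both argue against a larger amount of blood as the whole cause. This step cannot tell neutrophils in the liver tissue from more neutrophils in the same amount of blood, which stays open. After removing the relation to the acute phase score the neutrophil difference went from 1.77 to 0.53 (exact permutation p = 0.366). Housing or handling that goes with the first digit of the label stays open and cannot be told apart from treatment, since 0 first digits occur in both groups, and a response of the liver to the daily drugs also stays open as a hypothesis.

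The second pattern is the lower lists of fatty acid synthesis and lipid droplets, where displacement of reads by abundant acute phase transcripts would lower all other genes too, but with values per total reads, which do not centre it, the median log2 fold change of all genes was 0.002, which argues against it. A candidate explanation for fatty acid synthesis is coupling to the strength of the acute phase response: in the 6 treated livers the scores had r = −0.91 (exact permutation p = 0.0139, adjusted p = 0.111 over 10 relations; rho = −0.94, exact permutation p = 0.0167, adjusted p = 0.0834), r = −0.95 without 5_2 and 5_5, and r = −0.34 in the vehicle livers. The relation fails the correction, its bound was set after the value was seen, and 6 livers are too few to decide, so the coupling stays open. Removing the relation to the acute phase score took the fatty acid synthesis difference from −0.66 to −0.06 (exact permutation p = 0.597) and that of lipid droplets from −0.34 to −0.17 (exact permutation p = 0.01082), which for lipid droplets argues against that coupling as the whole cause. The same step left −0.31 at 0.01 for cholesterol synthesis, −0.26 at −0.04 for the tricarboxylic acid cycle, −0.18 at −0.06 for fatty acid oxidation and −0.27 at −0.10 for PPARα-responsive genes (exact permutation p = 0.944, 0.522, 0.439 and 0.251), but it also removes any treatment effect that the lists share, so it does not show coupling.

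The third pattern is the composition of the muscles at 24 h. RNA carried over from liver may account for the liver transcripts in the vehicle muscle: of the 30 most abundant liver transcripts among those that averaged under 5 FPKM in muscle at 40 d, 27 lay within 2-fold of a common 0.404% of their liver level, which is exactly the bound set for it after the values were seen. A vehicle muscle at 40 d, 3_2, had 0.508%, and the other muscles at 40 d at most 0.085%. Differences between pieces of muscle could account for the adipocyte, slow-twitch, fast-twitch and fatty acid synthesis lists, since 1, 8, 5 and 3 of the 15 pairs of vehicle muscles at 40 d differed by as much in the list means (1.25, 1.10, −0.44 and 0.67 at 24 h). For glycolysis 0 of 15 pairs did with the uncertain Gapdh and 3 of 15 without it. For fatty acid oxidation, the mitochondrial genome and the acute exercise list 0 of 15 did. Their list means at 24 h were 0.65, 0.91 and 0.80, against largest pair differences of 0.60, 0.78 and 0.60. For these lists a difference between pieces of muscle stays open as well. With 1 library per group, an early effect of the drugs stays open, as does stress at handling, since heat shock genes were higher too. Myh7 stood at 0.0663 FPKM in the vehicle and 0.139 in the treated muscle at 24 h, far below its level at 40 d. The slow-twitch list held 9 members at 24 h and 11 at 40 d. The muscles at 24 h and 40 d may thus be unlike pieces. The pairs at 40 d are therefore an unsure yardstick and decide nothing for the slow-twitch list or any other list here.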
